A study of Homo sapiens and Saccharomyces cerevisiae with 8 samples.

How the data were processed

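The series holds 8 samples. RNA was sequenced from 4 budding yeast (Saccharomyces cerevisiae) samples, 2 labelled H4K91E and 2 labelled wild type, and these 4 libraries were analysed. H4K91E stands for glutamate in place of the lysine at residue 91 of histone H4. The other 4 samples are ChIP-seq libraries of HepG2 cells, a human liver cancer line, 2 made with an antibody named H4K91 and 2 of input chromatin; they were not analysed here.

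Per the labels' protocols, RNA was harvested with TRIzol, enriched by oligo-dT selection or by rRNA depletion, fragmented, reverse transcribed from random primers, amplified by PCR and sequenced on a BGISEQ-500. The labels do not say which of the 2 enrichments was used for which library. Per the submitters' processing notes, the tools were BWA 0.7.17-r1188, deepTools 3.2.0, STAR 2.5.2b and featureCounts 1.6.2, and the genome builds were hg19 and sacCer3. Those notes assign no tool or build to an assay. The authors deposited 1 table of raw read counts per gene model and library, in the column layout of featureCounts per the file headers, with no normalization and no pooling. Its chromosome names and coordinates are those of yeast, and positions are given as in that table (sacCer3). The strand setting of the counting and the handling of reads that match several places are not given in the sources used here, so values of models that overlap another model on either strand, and of near-identical gene copies, are uncertain.

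The table lists 6125 gene models, of which 5983 are coding nuclear models, 123 noncoding models and 19 mitochondrial models, by accession prefix and chromosome. Model lengths are multiples of 3 for 98.6% of models, so those of the coding models are taken as coding lengths without untranslated regions. The models carry RefSeq accessions and no gene names. The name tables at hand cover human genes and matched 0 of the 6125 accessions, so the files used here do not pair the accessions with names. The histone genes, the gene sets and the strain and cell type checks planned by gene name, on 30 gene lists in all, were therefore not run. Of these lists, only the mitochondrial and noncoding models could be picked out by rule, and 3 mitochondrial models passed the count filter, too few for a list test. Gene models are given by position instead, with 2 accessions per direction.

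Total counts were 20318601 and 20286273 in the H4K91E libraries and 21161961 and 21160632 in the wild-type libraries. The counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 8.28 for the H4K91E pair and 5.90 for the wild-type pair over models with at least 10 counts, so each was used as a replicate of its own. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels give the groups the same replicate numbers but name no shared day or batch, and the numbers were not used as a block in the tests reported. Intervals on shares and ratios of counts are exact 95% binomial intervals and cover counting error only, since PCR copies were not marked.

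Group differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the filterByExpr filter by group, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The test covered 5905 models. Standard errors of log2 fold changes were derived from the F statistic, and the common biological coefficient of variation was 3.80%. A spread given for a median is the SD of that median over the 4 pairings of an H4K91E with a wild-type library, which share libraries. Genes within 20 kb of a chromosome end, and the noncoding models, were tested as lists with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and the calls near ends were compared with those of all other tested nuclear models by a 2-sided Fisher's exact test. The left end was taken as position 1 and the right end as the end of the last model listed on that chromosome. Genes were also split into 4 bins of equal size by mean log2 CPM. Random lists for comparison, 10000 each, were drawn gene by gene from the 50 models nearest in the matched property.

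The rule for single genes took the 10 higher and the 10 lower models with the largest absolute log2 fold change among those past the threshold, with both H4K91E libraries on the same side of both wild-type libraries and at least 10 CPM on average in the higher group; its part on histone genes could not be applied. This rule, the 20 kb distance, the bins, the tests and most alternative settings were fixed before the data were examined. Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, other low-count filters, an adjusted p of 0.01, leaving out mitochondrial and noncoding models, leaving out each library in turn, a replicate block, other distances and other set tests.

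The edgeR step was tested on simulated counts for this comparison with 5850 genes in the test. It recovered 82% of 50 genes changed 1.2-fold, 98% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 98% of 50 changed 4-fold, and it called 3 of 5654 unchanged genes. In these counts few genes changed, as many up as down, and genes varied independently with a single dispersion. The shares need not hold for the data, where 71.0% of models were called and large changes were nearly all increases.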

Results

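RNA-seq of budding yeast compared 2 libraries labelled H4K91E with 2 labelled wild type. Residue 91 of histone H4 is a lysine, and the series' title names glutarylation of this residue; glutamate, like a glutarylated lysine, carries a negative charge. The comparison asks which transcripts differ when the residue is glutamate. The libraries held between 20286273 and 21161961 counted reads over 6125 gene models, and 163, 170, 189 and 193 models had no read in the 2 H4K91E and the 2 wild-type libraries, respectively. Replicates were close, with a correlation of log2 CPM across genes of 0.997 for the H4K91E pair and 0.998 for the wild-type pair.

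Transcript levels differed widely between the groups, mostly by small factors, and the large changes were nearly all increases. Of 5905 tested models, 2158 were higher and 2037 lower in H4K91E, which is 71.0% of those tested. At least 2-fold changes were found for 452 higher and 34 lower models, and at least 4-fold changes for 134 higher and 2 lower models. Changes under 2-fold made up 88.4% of the calls. These calls come from edgeR's quasi-likelihood test with an adjusted p under 0.05 and 2 libraries per group. With library totals in place of TMM scaling, the median of all genes shifted by 0.15 on the log2 scale and the split became 3025 higher and 1230 lower, so 71.1% rather than 51.4% of the calls were higher. The near-even split of small changes therefore rests on the scaling. Of the 452 models that rose at least 2-fold, 31 overlap another model and 3 are mitochondrial.

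The most increased model, NM_001180315.3, lies at 461842 to 462516 on the plus strand of chromosome IV and is a single coding exon of 675 bases. It had 15832 and 15887 reads in the H4K91E libraries against 32 and 35 in the wild-type libraries. Its log2 fold change was 8.79 (SE 0.09), a 443-fold increase, with an edgeR adjusted p of 1.65e-18. Its neighbour on the left, at 458542 to 461247, had a log2 fold change of −0.24 (SE 0.06), and the next model on the right, at 463434 to 464996, one of 1.00 (SE 0.10). Among models of at least 10 CPM on average in the higher group, the limit set for single genes, the next largest increase was that of NM_001181128.1, which lies at 5312 to 5839 on chromosome VII, within the last 20 kb of that chromosome. Its counts were 205 and 233 in H4K91E against 1 and 3 in wild type, a ratio of 103 with a counting interval of 39.9 to 379. Its log2 fold change of 6.60 became 6.05 without wild-type replicate 1 and 7.52 without wild-type replicate 2. Weaker models with larger fitted changes were left out by this limit. The remaining 8 of the 10 most increased models above it had log2 fold changes from 3.69 upward. They included the model next to it at 2790 to 3932 on chromosome VII, with 865 and 884 reads against 8 and 18 and a log2 fold change of 5.97, or 6.66 without wild-type replicate 2. They also included models at 359702 to 360181 on chromosome VIII, with 361 and 373 reads against 7 and 9, and at 1223474 to 1224394 on chromosome IV, with 538 and 566 against 18 and 18. Of these 10 models, 3 lay within 20 kb of a chromosome end.

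A single model was almost lost from the H4K91E libraries. NM_001182869.1, a coding exon of 312 bases at 576727 to 577038 on the plus strand of chromosome XIV, had 10 and 11 reads in H4K91E against 9227 and 9106 in wild type. Its log2 fold change was −9.84 (SE 0.10), with an edgeR adjusted p of 1.65e-18, and the wild-type level was 929 times the H4K91E level, with a counting interval of 608 to 1502. The models beside it changed far less: the one transcribed away from it, at 575640 to 576050, had a log2 fold change of −0.28 (SE 0.05), and the one on its right, at 577205 to 578773, one of 0.40 (SE 0.06). The next largest decrease was that of NM_001182486.1 at 24037 to 25800 on chromosome XIII, with 4126 and 4436 reads against 19238 and 15254 and a log2 fold change of −2.10 (SE 0.09). The other 8 of the 10 most decreased models above the same limit fell by 1.37 to 1.82 on the log2 scale, and 1 of them, at 856442 to 857317 on chromosome XII, overlaps another model. None of the 10 lay within 20 kb of a chromosome end. The files used here do not tell which models encode histone H4 or are strain markers, and the labels do not say whether the strains differ other than at residue 91. The changes of the chromosome IV and XIV models are therefore not assigned to the substitution rather than to the making of the strains. Nor are the other differences between the groups given here, since the strains may differ in more than that residue.

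**Figure D1:**
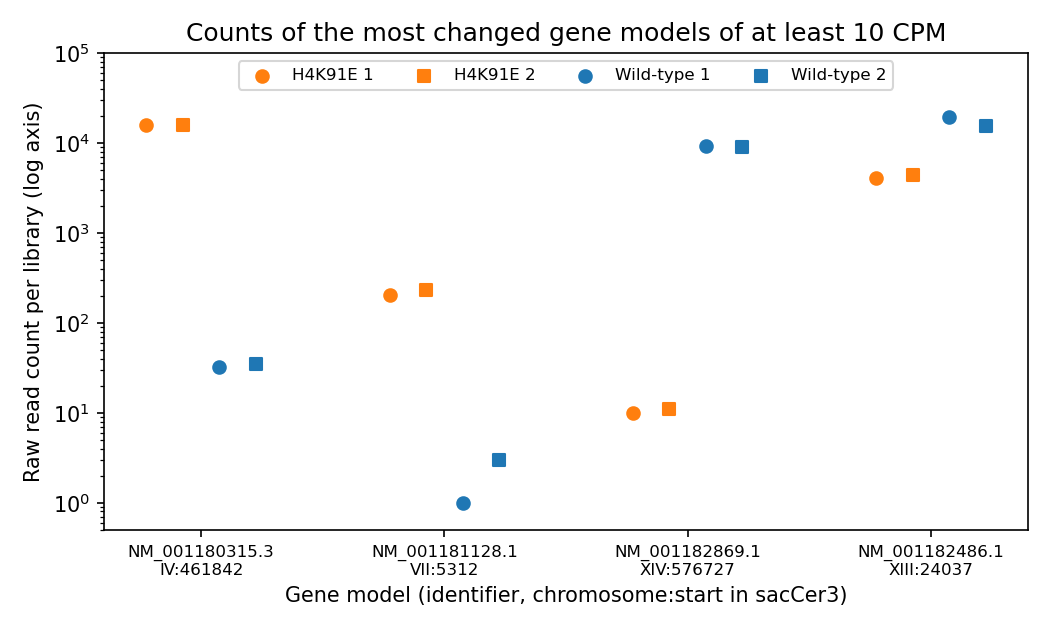
Raw read counts (log axis) of the 2 most increased and the 2 most decreased models, among those of at least 10 CPM in the higher group, in each of the 4 libraries, with 1 point per library; orange points are H4K91E and blue points wild type. The chromosome IV model goes from 32 and 35 reads in wild type to 15832 and 15887 in H4K91E, and the chromosome XIV model from 9227 and 9106 to 10 and 11.

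Genes near chromosome ends, where yeast chromatin is silenced in part, were higher in H4K91E as a group. Of 252 models within 20 kb of an end, 191 could be tested; 129 of these were higher, 21 were lower and 41 were not called, the same counts as when adjusted over the list alone. Their median log2 fold change was 0.70 (SD 0.02 over library pairs), or 1.63-fold, against 0.00 for the 5711 other nuclear models. At least 2-fold changes were found for 77 higher models and 1 lower model. Increases were widespread among the ends: 27 of the 29 ends with at least 3 tested models had a median above 0, and 25 of the 32 ends held a model at least 2-fold higher.

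The list stood above the other genes by camera (p = 8.23e-10; p = 0.0395 with an estimated correlation). Higher calls were more frequent within 20 kb than elsewhere, with 67.5% against 35.5% (Fisher's exact test, odds ratio 3.78, 95% interval 2.76 to 5.23, p = 1.48e-18), and lower calls less frequent, with 21 of 191 against 2016 of 5711 models (odds ratio 0.226, p = 4.95e-14). Fisher's test takes genes as independent, while some adjacent genes rose together. Its p-values and interval therefore do not measure the spread between samples. The median log2 fold change was 0.89 (SD 0.09) within 5 kb, 1.02 (SD 0.10) from 5 to 10 kb, 0.60 (SD 0.06) from 10 to 20 kb, 0.28 (SD 0.01) from 20 to 30 kb and 0.04 (SD 0.01) from 30 to 40 kb. Random lists of genes over 50 kb from an end, matched on wild-type reads per kb, had medians between 0.52 and 0.75 (central 95%), a range that includes 0.70. With only models of at least 10 CPM on average, the median was 0.38 and 70 models near ends were higher.

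**Figure D2:**
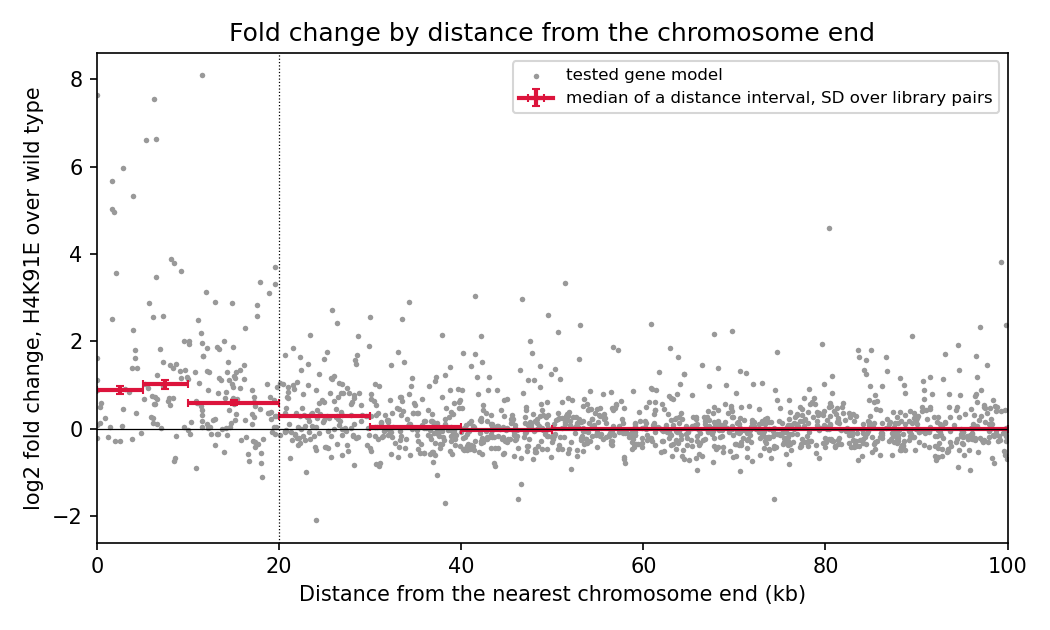
The log2 fold change (H4K91E over wild type) of each tested model within 100 kb of a chromosome end, as grey points, against the distance from that end in kb. Red bars are medians of distance intervals, with the SD over library pairs as the vertical error, and the dotted line marks 20 kb; the medians go from 0.89 and 1.02 in the first 10 kb to 0.04 between 30 and 40 kb.

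Some increases came in blocks of adjacent genes. The 6 tested models between 2790 and 11730 on chromosome VII were all at least 2-fold higher, with 1689 and 1708 reads together in H4K91E against 67 and 114 in wild type. Another 6 adjacent models, at 297049 to 308175 on chromosome III, had 3501 and 3666 reads against 884 and 959 and a median log2 fold change of 1.87; 2 of these 6 overlap another model, so reads may be shared between models. Further blocks lay at 11565 to 22685 on chromosome I with 5 models, at 8683 to 18566 on chromosome IV with 4 models and at 9597 to 14654 on chromosome XV with 4 models. In all, 15 blocks of at least 3 adjacent models at least 2-fold higher were found, 8 of them reaching within 20 kb of an end. The block at 461842 to 465383 on chromosome IV holds the most increased model. Shuffling the models within and outside the last 20 kb gave 7.38 blocks on average, with a permutation p of 0.002 over 10000 shuffles. This count was chosen after the data were seen, and the shuffles do not hold the expression level of neighbours.

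The weakly expressed genes were higher in H4K91E relative to the strongly expressed genes, which were lower under TMM scaling. In the lowest of 4 expression bins, up to 38.1 CPM, the median log2 fold change was 0.46 (SD 0.01) and 884 of 1477 models were higher against 175 lower. In the highest bin, from 163 CPM, it was −0.19 (SD 0.01) and 238 of 1476 models were higher against 888 lower. The middle bins had medians of 0.05 and −0.04. With library totals alone, which shift all genes up, the medians from the lowest to the highest bin were 0.61, 0.20, 0.11 and −0.04, so the third turned positive and the decrease of the strongly expressed genes nearly vanished. The lowest bin stood 0.65 (SD 0.01) above the highest, under TMM scaling and with library totals alone, and held 82.3% of the models that were at least 2-fold higher. With only models of at least 10 CPM, the difference was 0.42, and 255 rather than 452 models were at least 2-fold higher.

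**Figure D3:**
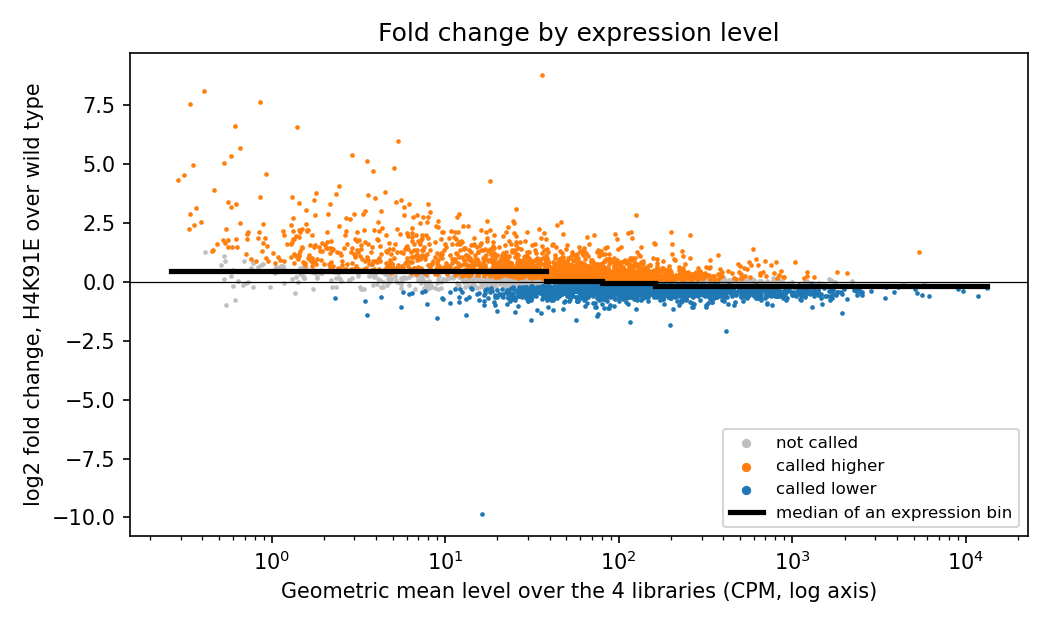
The log2 fold change (H4K91E over wild type) of each tested nuclear model against its geometric mean level over the 4 libraries in CPM (log axis), coloured by the edgeR call at an adjusted p of 0.05. Black lines span the 4 expression bins at their medians of 0.46, 0.05, −0.04 (0.11 with library totals alone) and −0.19, and the low point at a log2 fold change of −9.84 is the chromosome XIV model.

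Noncoding RNAs, a list fixed by accession prefix, were higher as a class. Of 93 tested noncoding models, 66 were higher, 2 lower and 25 not called, the same counts of higher and lower models as when adjusted over the list alone. Their median log2 fold change was 0.65 (SD 0.07); 22 were at least 2-fold higher and 0 at least 2-fold lower. They made up 0.142% (95% interval 0.141 to 0.144) and 0.140% (0.138 to 0.141) of the H4K91E reads, against 0.0909% (0.0896 to 0.0922) and 0.0964% (0.0951 to 0.0977) of the wild-type reads. The list stood above the other genes by camera (p = 1.35e-06, or p = 0.0354 with an estimated correlation). Random lists of coding genes matched on length and wild-type level had medians from 0.28 to 0.61 (central 95%), around 0.49. Part of the rise was thus shared with such coding genes. The protocol names both poly(A) selection and rRNA depletion, and how far each class was recovered in each library is not known. Noncoding genes can be multi-copy, so values of single models are uncertain and are not given. With only models of at least 10 CPM, 28 noncoding models remained in the test, with a median of 0.41.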

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

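The weighing of the noncoding models against short models was fixed before its result was seen; the look at RNA without poly(A) tails was chosen after the noncoding result was seen. Reads from the 19 mitochondrial models were not described with the nuclear genes, and they were found almost only in the H4K91E libraries, with 87 and 88 reads against 2 and 3 in the wild-type libraries. Per counted read, the H4K91E libraries held 36.5 times as many (counting interval 15.3 to 114), spread over 14 models. Of the 19 models, 3 passed the count filter and are among the models called at least 2-fold higher; the others, outside the test, held 40 and 33 of these reads. Both libraries of each group took the same side, but these are small numbers beside the 20318601 and 20286273 counted reads.

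The pattern to weigh is the increase of RNA classes that often lack long poly(A) tails, the noncoding models with a median log2 fold change of 0.65 and these mitochondrial reads. Short length and weak expression are argued against as the whole cause of the noncoding increase: random lists of coding genes matched on length and mean level had medians from 0.28 to 0.59 (central 95%), below 0.65, and 57 of 10000 lists reached it. Matched on length and wild-type level, they spanned 0.28 to 0.61. Another recovery of RNA without poly(A) tails in the H4K91E preparations cannot be told apart from an effect of the genotype. Which models lack a tail is not known, and the labels do not say how preparations were shared between the groups. The 2 noncoding models called lower do not decide it, since they may or may not have tails. A different content of mitochondrial DNA or RNA in the strains also stays open, as untested.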

How the results depend on the processing

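No count, list median or bin difference changed direction or lost its call under the alternatives run, while the median of the third expression bin went from −0.04 to 0.11 and that of the highest from −0.19 to −0.04 with library totals alone. The 20 single genes kept their sign and call wherever they were tested, with an adjusted p of at most 0.000152: in 12 of 14 settings all were tested, with at least 10 CPM 15 of them and without overlapping models, a setting chosen after seeing the data, 19. The genes near ends passed the camera test under every scaling, filter, distance and left-out library tried, with medians from 0.38 (at least 10 CPM) to 0.94 (10 kb). The noncoding list passed it in each setting too, with medians from 0.41 to 0.80. DESeq2 called 1855 models higher and 1863 lower, and limma-voom 2162 and 2039. Library totals alone gave 1230 lower models, 18 of them at least 2-fold, because the median shifted. At least 10 CPM on average left 255 models at least 2-fold higher, 70 higher near ends and a bin difference of 0.422, with weak genes removed. Other distances changed the list itself, with 56 models higher within 10 kb and 204 within 30 kb. The bin difference was 0.687 with no filter and 0.604 without mitochondrial and noncoding models, and 0.604 to 0.696 with 1 library left out, where the lone library was assumed to vary like the other group; the cause was not tested. Other settings chosen after seeing the data gave 0.764 with bins by wild-type level, 0.493 with bins by H4K91E level and 0.557 without genes within 50 kb of an end, and 0.699 for the median near ends without the left end of chromosome VII. The replicate block gave 2277 higher and 2184 lower models; same-numbered samples deviated together weakly (correlation across genes 0.23 at 10 CPM or more, 0.11 over all), but with 2 pairs the numbers do not pair the samples. The alternatives planned for the histone genes and the other gene sets were not run, for want of gene names. At this depth 82% of simulated 1.2-fold changes were recovered, so a missing call does not show equal levels.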

Other observations

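Tests of this part chosen only after the result was seen are the matches on wild-type level and on wild-type reads per kb, the share of ends, the bins without genes near ends, the comparison by exon number, the chromosome medians, the neighbouring genes and the divergent pairs; bins by the H4K91E level were added after the data, but not their own result, were seen. Coding genes with several exons were more often lower than higher: of 285 tested, 157 were lower and 67 higher, with a median log2 fold change of −0.18 (SD 0.03). The large changes went the other way, with 22 of them at least 2-fold higher and 2 at least 2-fold lower. Random lists of single-exon coding genes with the same mean level had medians from −0.10 to 0.01 (central 95%), and lists matched on coding length too had medians from −0.12 to −0.03; in both matches 10000 of 10000 lists lay at or above −0.18. The median stayed below 0 under each scaling and came to −0.03 with library totals alone, against 0.16 for all genes.

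The model lost from chromosome XIV has a counterpart of equal length. It is transcribed away from a model of 411 bases, and the table holds 1 other divergent pair of a 312-base and a 411-base model, on chromosome II. There the 312-base model, at 255373 to 255684, had 22685 and 23421 reads in H4K91E against 11835 and 12061 in wild type, a log2 fold change of 0.86 (SE 0.05, edgeR adjusted p 3.04e-09), or 1.81-fold. Its 411-base partner, at 256331 to 256741, had a log2 fold change of 0.27 (SE 0.06, edgeR adjusted p 0.000647). This pair was picked after the values were seen, and how reads that match both 312-base models were counted is not known.

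Chromosomes did not shift as wholes by more than a small amount. Over genes at least 50 kb from an end, the chromosome medians ran from −0.09 for chromosome I to 0.13 for chromosome III. The latter lay above the central 95% of random lists matched on mean level (upper bound 0.11), with 99 of 10000 lists reaching it, but it was picked as the highest of 16 chromosomes. With library totals alone, which shift the median of all genes by 0.15, the chromosome III median was 0.28. Away from the ends, the fold changes of neighbouring coding genes went together across genes for tandem pairs (Spearman's rho 0.137 over 2418 pairs, permutation p 1e-04, the smallest that 10000 permutations can give, adjusted 3e-04 over 3 arrangements). Divergent pairs had a rho of 0.070 (1322 pairs, adjusted permutation p 0.015) and convergent pairs 0.035 (1314 pairs, adjusted permutation p 0.2). The difference between both wild-type libraries gave 0.026 for tandem and 0.100 for divergent pairs, so the divergent value is no larger than that between replicates. Genes are not independent replicates.

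The first pattern weighed is the increase near chromosome ends. A few ends as carriers of a rise above 0 are argued against by the 27 of 29 ends with a median above 0. Lists of genes over 50 kb from an end, matched on wild-type reads per kb, had a median of 0.62. The share of ends therefore cannot tell whether an excess over genes of that read density sits in a few ends. Weak genes by mean level are argued against by the median of 0.70, above the 0.24 to 0.49 of lists matched on mean level. That level, however, holds the H4K91E values themselves. Lists matched on wild-type level spanned 0.37 to 0.62, with 10 of 10000 reaching 0.70, but 919 of 10000 lists matched on wild-type reads per kb, which also takes in coding length, reached it, so a rise of all genes of equally low read density, wherever they lie, stays open. A uniform background of reads in the H4K91E libraries is not settled. The prediction for it, fixed before the result was seen, was met. The 5th percentile of H4K91E reads per kb was 246, more than the median gain of 174 reads per kb of the genes near ends called higher. Those genes were selected for rising, and the median gain over all tested genes near ends was 92. A count outside that prediction found 194 tested nuclear models with fewer reads per kb than 174, which an even background of that size forbids. They argue against that size for those models, unless reads that match several places were dropped there. A smaller or uneven background stays open. Whether the increase goes beyond that of weakly transcribed genes in general depends on how they are matched, and an effect of the genotype itself was not tested apart from these.

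The second pattern is the rise of weak relative to strong genes; the fall of the strongest bin itself rests on TMM scaling, at −0.19 against −0.04 with library totals alone. Binning on a level that holds the change itself is argued against as its whole cause by the difference of 0.49 with bins by the H4K91E level alone, which works against the pattern. Genes near ends are argued against as its whole cause by the difference of 0.56 without genes within 50 kb of an end. For a uniform background, the 246 reads per kb also exceed the median gain of 181 of the genes in the lowest bin called higher. The prediction fixed beforehand for such a background was thus met here too, again over genes selected for rising. The same 194 models held fewer than 174 reads per kb, so an even background of 181 is argued against for them in the same way. A smaller or uneven background stays open here too. An added background, or transcription across the genome that acts like one, could raise weak genes by a large factor and strong genes by a small one, and the tables do not separate these from an effect of the genotype.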
